A study of Mus musculus with 5 samples.

How the data were processed

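RNA from mouse spleen and gut was measured on 5 Affymetrix arrays, 1 per group. The groups were spleen and gut of transplanted mice left untreated, spleen and gut of transplanted mice given the antibody 3D10, and spleen labelled as coming from a mouse without a transplant. Per the labels' protocols, Balb/c recipients received T cell depleted bone marrow cells and T cells of the B6 background in a ratio of 5 to 1, tissue was taken 9 days later into an RNA stabilisation solution, and 500 pg to 2 ng of total RNA was amplified with a kit for very small inputs. The 4 arrays of transplanted mice were of 1 type, with 41345 probe sets (whole-transcript arrays). The array labelled no BMT spleen was of an older type, with 45101 probe sets, and was alone on it.

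The deposited values are log2 expression values made with RMA, which corrects background, normalises arrays by quantiles and summarises probes, per the submitters' processing notes. The version of RMA, the arrays it was run on together and the annotation it used are not given in the sources used here. An array has no count of reads, and precision was limited by the number of arrays and, for genes near the background, by signal. Of the probe sets, 36.07% (14912) held exactly the same value in the 2 transplanted spleen arrays and 46.52% (19233) in the 2 gut arrays, while 0 did so between a spleen and a gut array. Levels were therefore compared within a tissue, and spleen was set against gut only to check the tissue labels. Exact ties make a difference of 0 common, so that the medians of many gene lists were exactly 0.

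Probe sets were named through the platform annotation. On the arrays of transplanted mice 23521 probe sets had 1 gene, 1814 had several and 16010 had none, and on the other array these numbers were 34958, 932 and 9211. Only probe sets with 1 gene were used. Where a gene had several, the probe set with the highest mean was taken, which left 22180 genes on the first type of array and 18195 on the other. A gene passed the level filter of a comparison when the higher of its 2 values was at least 3.746, the median of all gene values. Members of the gene lists that had no probe set of their own were not used here.

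With 1 array per group there was no replicate check and no test of any difference between 2 arrays. Differences are 3D10 minus untreated on the log2 scale, and genes past the filter were counted at 2-fold and over. Where the lower of the 2 values lay under the filter, the printed difference is no exact size and may be too large or too small. The filter is no estimate of the background. For 49 gene lists (cell types, immune pathways, epithelial lineages, metabolism, other tissues and RNA quality) the median difference of the measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its median lay outside the 2.5 to 97.5 percentile range of those random lists, which describes these arrays and is no test of the treatment. Among so many lists some stand apart by chance. Exact ties also narrow the range of the random medians, for some lists to 0.0 at both ends. A small median can then stand apart, and its percentile does not measure the size of a shift. The only test was a limma model (limma 3.58.1 in R 4.3.3, eBayes with a trend, Benjamini-Hochberg adjustment) over the 4 arrays of transplanted mice with terms for tissue and treatment. It has 1 residual degree of freedom, so its spread is how far the 3D10 difference varies between the 2 tissues. No labels say whether spleen and gut came from the same mice, so this spread may not measure the spread between mice. The array labelled no BMT spleen was compared through percentile ranks among the 17028 genes found on both types of array. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

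The gene lists, the designs, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per tissue, the 10 genes with the largest positive and the 10 with the largest negative difference past the filter and at least 2-fold. It left out predicted or unnamed loci, small RNA genes, olfactory and vomeronasal receptors and antigen receptor segments, the last of which were summarised as a class. It added up to 4 members per described list with the largest absolute difference past the filter, the genes of TIM-1, TIM-3 and TIM-4, and up to 10 genes at least 2-fold in the same direction in both tissues. For the array labelled no BMT spleen it took up to 4 members per list with the largest rank difference.

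Both steps were tested on simulated data. Noise had an SD of 0.342 per array, taken from the 3D10 minus untreated differences of the spleen genes that were not exact ties. Any treatment difference and the difference in range of the 2 arrays are part of it, and the simulated arrays held no ties. Of 200 genes raised by 2 on the log2 scale among 22180, 97.5% were counted. Noise alone carried 259 other genes to at least 2-fold higher, and those it carried to at least 2-fold lower were not counted. The 259 is thus no estimate of false counts on the real arrays. Of lists drawn without a shift 3.0% stood apart, and of lists raised by 0.5 the share was 96.0%. The limma step recovered 100% of 200 changed genes among 11614 with 9 false calls, at noise of SD 0.253 that was alike for all genes. On the real arrays the fit drew only 0.5453 prior degrees of freedom from the other genes, beside its 1 residual degree. The recovery therefore does not show what this step could find on them. Alternatives covered loess and quantile normalisation of each pair, centring on the median, no level filter and a filter at the upper quartile (5.233), the mean of a gene's probe sets, thresholds of 1.5-fold and 3-fold, list means in place of medians, members past the filter alone, random lists without matching, and other limma settings. No count could be repeated without an array that stands apart, since each group has only 1.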

Results

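The study asked what an antibody against TIM-1 does to gene expression in recipients of an allogeneic bone marrow transplant (BMT). TIM-1, encoded by Havcr1, is a cell surface receptor of immune and epithelial cells, and 3D10 is a monoclonal antibody against it. The mice received 3D10 on day -1 and on days 3, 7, 11 and 17 after transplantation, while tissue was taken on day 9, so the last 2 listed doses lie after the harvest. Giving Balb/c mice marrow and T cells of the B6 background is a standard way to provoke graft-versus-host disease, in which donor T cells attack recipient tissues such as the gut. There was 1 array in each of 5 groups, so no value below has a replicate error, and differences between 2 arrays include those between mice, dissections and RNA samples.

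The tissue labels of the 4 arrays of transplanted mice held. All 23 measured enterocyte genes were higher in the untreated gut than in the untreated spleen, and 21 were higher in the 3D10 gut than in the 3D10 spleen. The 13 smooth muscle genes were higher in gut on both pairs. Erythroid genes, which are abundant in the blood-forming mouse spleen, had median log2 values of 4.98 and 5.81 on the untreated and 3D10 spleen arrays and of 3.59 and 3.78 on the gut arrays. B cell genes were low in all 4, with medians of 3.43 and 3.34 in spleen.

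The target itself gave little signal. Havcr1 had log2 values of 1.79 untreated and 1.71 with 3D10 in spleen, and of 2.14 on both gut arrays, all below the level filter. Havcr2 (TIM-3) was at 3.45 on both spleen arrays and at 3.26 on both gut arrays, and Timd4 (TIM-4) was at 2.54 and 2.46 in the same way. Timd2 differed by 0.00 in spleen and by -0.10 in gut. The arrays thus hold no measurable difference for the TIM genes, at a level where a difference could not be seen.

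In spleen, genes of cell division and of the interferon response were higher with 3D10, and genes of the small intestine's absorptive cells were lower. Of all genes past the filter in spleen 7.53% were at least 2-fold higher and 0.99% lower, and past the upper quartile filter 15.93% and 0.85%. An absence of lower members is therefore not particular to the lists below. The cell cycle list had a median difference of 0.82 (percentile 99.93 among matched random lists, whose own median was 0.46). Of its 28 members 10 were at least 2-fold higher while 0 were lower. Bub1, a mitotic checkpoint kinase, was higher by 1.52, the replication helicase subunit Mcm5 by 1.41, the kinetochore motor Cenpe by 1.30 and the ribonucleotide reductase subunit Rrm1 by 1.28. The type I interferon list had a median of 0.53 (percentile 99.72), and 3 of 21 members past the filter were at least 2-fold higher and 0 lower, with Oasl2 at 1.35, the viral RNA sensor Ifih1 at 1.27, the transcription factor Irf7 at 1.15 and Oas2 at 0.96. The interferon gamma list had a median of 0.47 (percentile 98.64), and 4 of 18 were at least 2-fold higher and 0 lower, with the immunity-related GTPases Iigp1 at 1.85 and Igtp at 1.38, the guanylate-binding protein Gbp7 at 1.78 and the peptide transporter Tap1 at 1.08. After loess scaling these 3 lists still stood apart, at 0.33, 0.38 and 0.35 in this order, and the type I list fell short (0.34, percentile 96.06) when a gene's probe sets were averaged. The erythroid list was at 0.42 within the random range as deposited (percentile 82.56) and stood apart after loess (0.39, percentile 99.61), with Rhag (2.36), Tfrc (1.83), Car1 (1.68) and Car2 (1.32) highest. Which cells the division genes came from, red cell precursors among them, was not analysed here.

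Counted by size, 790 genes were at least 2-fold higher and 104 at least 2-fold lower with 3D10 in spleen, among 10487 past the level filter. In 101 and 62 of them the lower value lay under the filter, so that the size of the difference is not exact. The 2 spleen arrays differed in range, with an SD across genes of 1.43 untreated and 1.63 with 3D10, and the split depended on the scaling. Loess gave 396 higher and 167 lower, so that the share of higher genes went from 88.4% to 70.3%, and quantile normalisation gave 290 and 169, a share of 63.2%. The largest positive differences as measured were those of the RNA-binding protein Tardbp (2.73), the ubiquitin ligase subunit Skp1 (2.41), the red cell Rh-associated glycoprotein Rhag (2.36) and the chemokine Ccl3 (2.34). They were followed by the acyl-CoA thioesterase Acot1 (2.23), Atp8b4 (2.23), Ivns1abp (2.21), the activating IgG receptor Fcgr4 (2.19), Shtn1 (2.18) and the RNA helicase Ddx5 (2.11). The largest negative differences as measured were those of Apoa4 (-2.54), Cypt1 (-2.26), Fbxw16 (-2.16), Rbx1-ps (-2.13), sucrase-isomaltase Sis (-2.06), Apoa1 (-2.02), intestinal alkaline phosphatase Alpi (-1.98), Zfp747 (-1.82), Serpina1c (-1.73) and Mettl7a3 (-1.62). Those of Tardbp, Ccl3, Acot1, Apoa4, Fbxw16, Rbx1-ps, Sis, Alpi and Serpina1c have a lower value under the filter, so the order is not exact. Fbxw16 (3.94), Rbx1-ps (3.94) and Serpina1c (3.79) lay only just above the filter on the untreated array as well.

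Enterocyte genes made up a clear group among the lower ones in spleen. The enterocyte list had a median of -0.41 (percentile 0.0), 19 of 23 members were below 0 and 0 above, and 5 of the 7 past the filter were at least 2-fold lower. The fibroblast and matrix list (-0.12, percentile 0.18), the tight junction list (-0.10, percentile 0.51) and the goblet cell list (-0.18, percentile 2.37) also stood apart as lower, by small amounts and with members in both directions. None of the 3 held under every setting, with percentiles of 5.87 for fibroblast genes with list means, 2.89 for tight junction genes after loess and 23.96 for goblet cell genes past the filter alone. The random range of the fibroblast list was 0.0 to 0.0, so its percentile says little about size. Postn was higher by 1.43, Mmp2 and Col5a1 differed by -0.74 and -0.73 and Sparc by 0.40. Among tight junction genes Cldn1 was higher by 1.53 and F11r by 0.94, while Pigr differed by -0.79 and Tjp3 by -0.49. Of the goblet cell genes Klk1 was higher by 1.58, and Atoh1, Spdef and Clca1 differed by -0.29, -0.22 and -0.17.

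The T cell, CD8 and cytotoxic, Th1, Th2, Th17, regulatory T cell and T cell activation lists lay within the range of random lists in spleen. Their medians of 0.00 do not show that the genes were alike, because 9592 of the 22180 genes had exactly the same value on both spleen arrays. In the T cell list 9 of 13 members were such ties, with 2 above 0 and 2 below, and in the T cell activation list 8 of 17, with 8 above (Cd69 at 0.68 and Cd274 at 0.66 among them) and 1 below. Members that differed included the Th1 transcription factor Stat4 (1.11), Cst7 (0.97), granzyme gene Gzmb (0.68), Cd44 (0.90) and the regulatory T cell factor Foxp3 (-0.92). The T cell activation list stood apart after loess (0.04, percentile 98.42). Loess moved its tied member Havcr2 from 0.00 to 0.04 as well, so this median may only reflect how loess treats ties. The natural killer list was at -0.13 and the chemokine, chemokine receptor and inflammatory cytokine lists at 0.00, where Ccl3 and Ccl9 (1.06) were the members at least 2-fold higher among chemokines. Monocyte and macrophage genes had a median of 0.42 (percentile 96.98, and 98.46 with members past the filter alone), with Hmox1 at 1.69, Mrc1 at 1.68, Slc40a1 at 1.37 and Vcam1 at 1.21. The neutrophil list was at 0.42 as deposited, within the range of random lists (percentile 15.11), whose own median was 0.55, and stood apart as lower after loess (-0.41, percentile 0.43). Of 17 immunoglobulin segments past the filter 10 were at least 2-fold higher and 1 lower, and the 23 measured had a median of 0.79 (percentile 100), while 9 T cell receptor segments had a median of 0.00.

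The other lists lay within the random range in spleen. Medians were 0.46 for ribosomal proteins, 0.43 for MHC class I, 0.36 for ER stress, 0.22 for fatty acid oxidation, 0.21 for mitochondrial respiration, 0.07 for megakaryocyte and platelet, 0.04 for immediate early and heat shock and 0.02 for p53 and apoptosis genes. They were -0.08 for xenobiotic metabolism, -0.07 for smooth muscle and -0.02 for sex-linked genes, of which Xist alone passed the filter and differed by 1.41 (0.93 after loess) in spleen and by 0.78 in gut. With members past the filter alone the xenobiotic (percentile 1.3) and smooth muscle (percentile 2.13) lists stood apart as lower, as did the mitochondrial list after loess (-0.23, percentile 1.66). Loess also took the MHC class I (-0.25, percentile 3.14), ribosomal (-0.085) and immediate early (-0.058) medians below 0, within the random range. As deposited, random lists matched to the ribosomal and MHC class I lists had medians of 0.373 and 0.475 themselves. The B cell, plasma cell, dendritic cell, mast cell, MHC class II, progenitor, colonocyte, Paneth cell, intestinal stem cell, enteroendocrine, endothelial, enteric neuron, pancreas, adipocyte, liver and cholesterol lists had medians of 0.00, to which exact ties contribute.

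**Figure D1:**
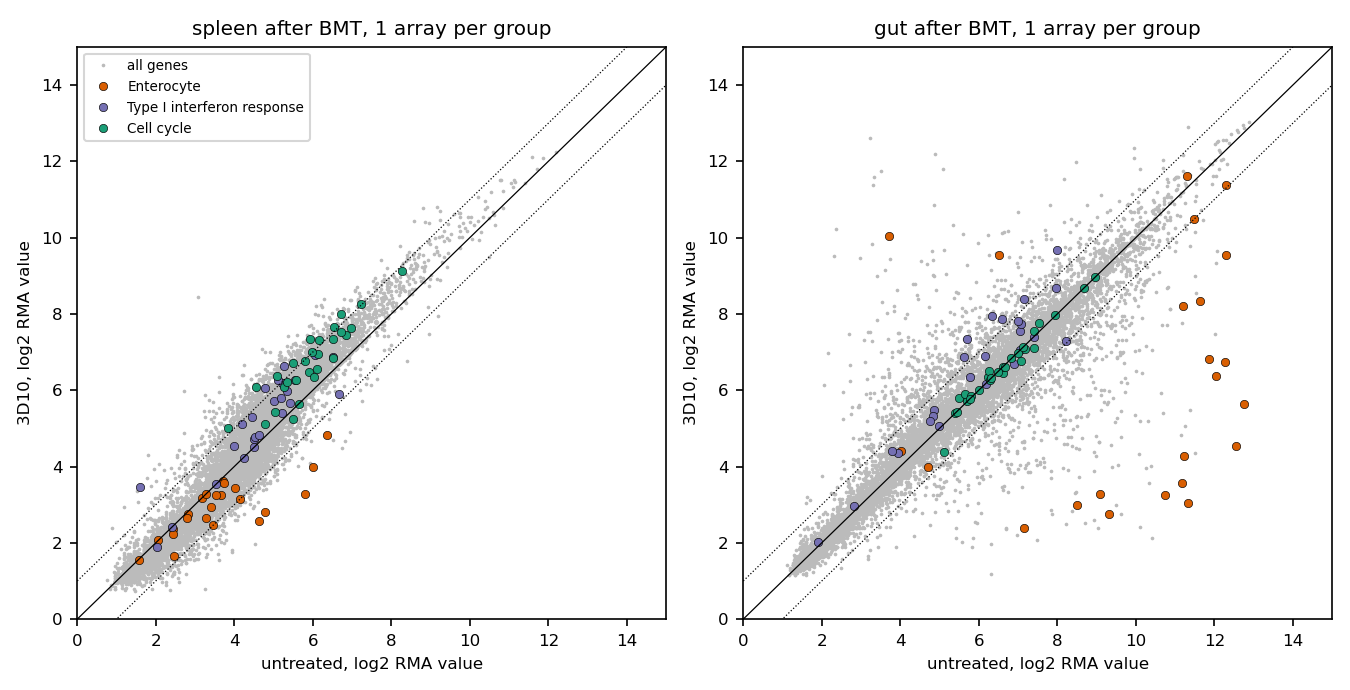
Log2 RMA value of each gene on the untreated array (horizontal axis) and the 3D10 array (vertical axis) in spleen (left) and gut (right), with equality as a solid line and 2-fold differences as dotted lines. Enterocyte genes lie mostly below the line, with list medians of -0.41 in spleen, where 4 of 23 lie on it, and -5.04 in gut, where 4 lie above it, type I interferon genes lie mostly above it (0.53 and 0.59), and cell cycle genes lie mostly above it in spleen (0.82), while in gut 9 of 28 lie above it, 7 below and 12 on it (0.00).

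In gut, the arrays differed most in the genes of absorptive epithelium. The enterocyte list had a median difference of -5.04 with 3D10 (percentile 0.0), and 16 of its 23 members were at least 2-fold lower while 2 were higher. The fatty acid binding protein Fabp1 differed by -8.28, Sis by -8.02, the lipoprotein assembly protein Mttp by -7.60 and the glucose transporter Slc2a2 by -7.47. All but Sis came under the filter on the 3D10 array, so that the sizes of their drops are not exact. Colonocyte genes had a median of 1.08 (percentile 99.98), with the carbonic anhydrases Car1 at 9.36 (no exact size, with the untreated value under the filter) and Car4 at 2.52, Guca2a at 2.13 and Slc37a2 at -2.64. Goblet cell genes had a median of 1.34 (percentile 100), and 7 of 11 were at least 2-fold higher, among them Retnlb (8.24, no exact size either), Klk1 (3.36), Clca1 (2.40) and Agr2 (1.69).

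By size, 670 genes were at least 2-fold higher and 594 lower with 3D10 in gut, among 12542 past the filter, and in 111 and 91 of them the lower value lay under it. The highest as measured after Car1 and Retnlb were the amino acid transporter Slc6a14 (8.07), Ly6g (7.87), Cyp2c55 (7.31), the gasdermins Gsdmc2 (7.21) and Gsdmc3 (6.51), Sptssb (6.54), the ileal bile acid transporter Slc10a2 (6.34) and the antimicrobial Ang4 (6.01). The lowest as measured were Cyp2b10 (-8.30), Fabp1, Sis, Mme (-7.67), Mttp, Slc2a2, Enpp3 (-7.14), Apoa4 (-7.11), Apoa1 (-6.96) and the urea cycle enzyme Cps1 (-6.77). Apart from Cyp2c55, Ang4, Sis, Enpp3, Apoa4 and Apoa1 these genes have a lower value under the filter, so the order is not exact. In the same pair of arrays genes that mark stretches of the gut went different ways. Of 15 small intestine genes 9 were at least 2-fold lower and 1, Mmp7 (1.41), was higher (median -2.49). The 7 ileum genes had a median of 1.09, the 15 measured colon genes one of 0.30 (percentile 99.99, 4 at least 2-fold higher and 0 lower, and 0.56 over the 10 past the filter), and 15 genes shared by the whole intestinal epithelium one of 0.26. These 4 lists were chosen after the gut values had been seen.

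Interferon genes were higher with 3D10 in gut too. The interferon gamma list had a median of 0.62 (percentile 100), 8 of 21 members past the filter were at least 2-fold higher and 0 lower, and Gbp4 (3.08), Iigp1 (2.44), the tryptophan-degrading enzyme Ido1 (2.35) and the checkpoint ligand Cd274 (2.20) led it. The type I interferon list had a median of 0.59 (percentile 100), with 6 of 23 past the filter at least 2-fold higher and 0 lower, and with Irf7 at 1.69, Isg15 at 1.65, Oasl2 at 1.63 and Ifit1 at 1.27. MHC class II genes had a median of 0.32 (percentile 99.69), with H2-Aa at 1.03, H2-Ab1 at 0.64, H2-Ob at 0.42 and H2-Eb1 at 0.36. The monocyte and macrophage list had a median of 0.28 (percentile 100, with a random range of 0.0 to 0.0), although Slc40a1 (4.25) and Ly6c2 (2.48) were higher and Lyz1 (-5.51), which Paneth cells also express, and Mertk (-2.03) lower. With list means in place of medians these last 2 lists came to percentiles of 94.17 and 93.78, within the random range.

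Muscle, matrix and stress genes were higher in the 3D10 gut as well. Smooth muscle genes had a median of 1.31 (percentile 100), with Acta2 at 2.05, Myh11 at 1.75, Cnn1 at 1.68 and Actg2 at 1.48. Fibroblast and matrix genes had a median of 0.69 (percentile 100), with Dcn at 3.83, Postn at 2.59, Loxl1 at 1.60 and Sparc at 1.44. Enteroendocrine and tuft cell genes had a median of 0.22 (percentile 99.97), with neurotensin Nts at 4.80, Tph1 at 2.70, Chgb at 2.33 and Chga at 2.16. The enteric neuron list was at 0.07 (percentile 99.05), with Snap25 at 1.14 and Vip at 0.55, but at percentile 95.06 with list means. Immediate early and heat shock genes, which respond to handling of tissue, had a median of 0.36 (percentile 99.96), with Hspa1b at 3.53, Hspa1a at 2.61, Dusp1 at 1.96 and Jun at 1.91.

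The xenobiotic, fatty acid oxidation and mitochondrial respiration lists stood apart as lower in the 3D10 gut. The xenobiotic and bile acid list had a median of -1.15 (percentile 0.0), with 9 of 17 members at least 2-fold lower, among them Cyp2b10, Cyp3a11 (-4.75) and Cyp2d26 (-3.35), and 5 at least 2-fold higher, among them Cyp2c55. The fatty acid oxidation list had a median of -0.60 (percentile 0.0), with Fabp1, Cd36 (-3.57), Angptl4 (-3.55) and Ehhadh (-1.67) lower. Mitochondrial respiration genes had a median of -0.29 (percentile 1.02), with Uqcrc1 at -0.75, Cyc1 at -0.67, Ndufa4 at -0.54 and Atp5a1 at -0.43, although with list means it came to percentile 20.41. The pancreas list was at -0.16 (percentile 0.01, with a random range of 0.0 to 0.0), but its members past the filter had a median of 0.04, and Spink1 (-3.48) was the only one at least 2-fold lower.

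Exact ties, 11560 of the 22180 genes on the gut pair, weigh on the medians here too, so that a median of 0.00 does not show that a list was alike. It was 0.00 for the T cell, CD8 and cytotoxic, natural killer, Th1, Th2, Th17, regulatory T cell, T cell activation, B cell, plasma cell, chemokine, chemokine receptor and inflammatory cytokine lists. Among chemokines 13 were above 0 and 7 below, with 4 at least 2-fold higher and 1 lower, and those past the filter came to percentile 96.96. Members that differed by over 2-fold included Maf (-1.83), Ikzf2 (1.97), Cd44 (1.59), Ccl25 (-2.49), Ccl8 (2.04), Cxcl11 (1.62), Cxcl9 (1.40) and Il18 (-2.85). Other lists within the random range were cholesterol synthesis (0.16), tight junction (0.11), p53 and apoptosis (0.04), MHC class I (0.04), ribosomal proteins (0.04) and Paneth cell (-0.05). Cell cycle, neutrophil, dendritic cell, mast cell, erythroid, megakaryocyte, progenitor, intestinal stem cell, endothelial, adipocyte, liver, ER stress and sex-linked lists had medians of 0.00. With members past the filter alone the adipocyte (1.06, percentile 99.84, with Fabp4 at 3.11, Lpl at 1.93 and Cidec at -1.38), dendritic cell (0.56, percentile 97.94) and progenitor (0.32, percentile 98.92) lists stood apart as higher and the endothelial list as lower (-0.04, percentile 1.98). Among single genes, the stem cell gene Olfm4 differed by -5.55 and the Paneth cell list held Ang4 and Lyz1 in opposite directions.

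**Figure D2:**
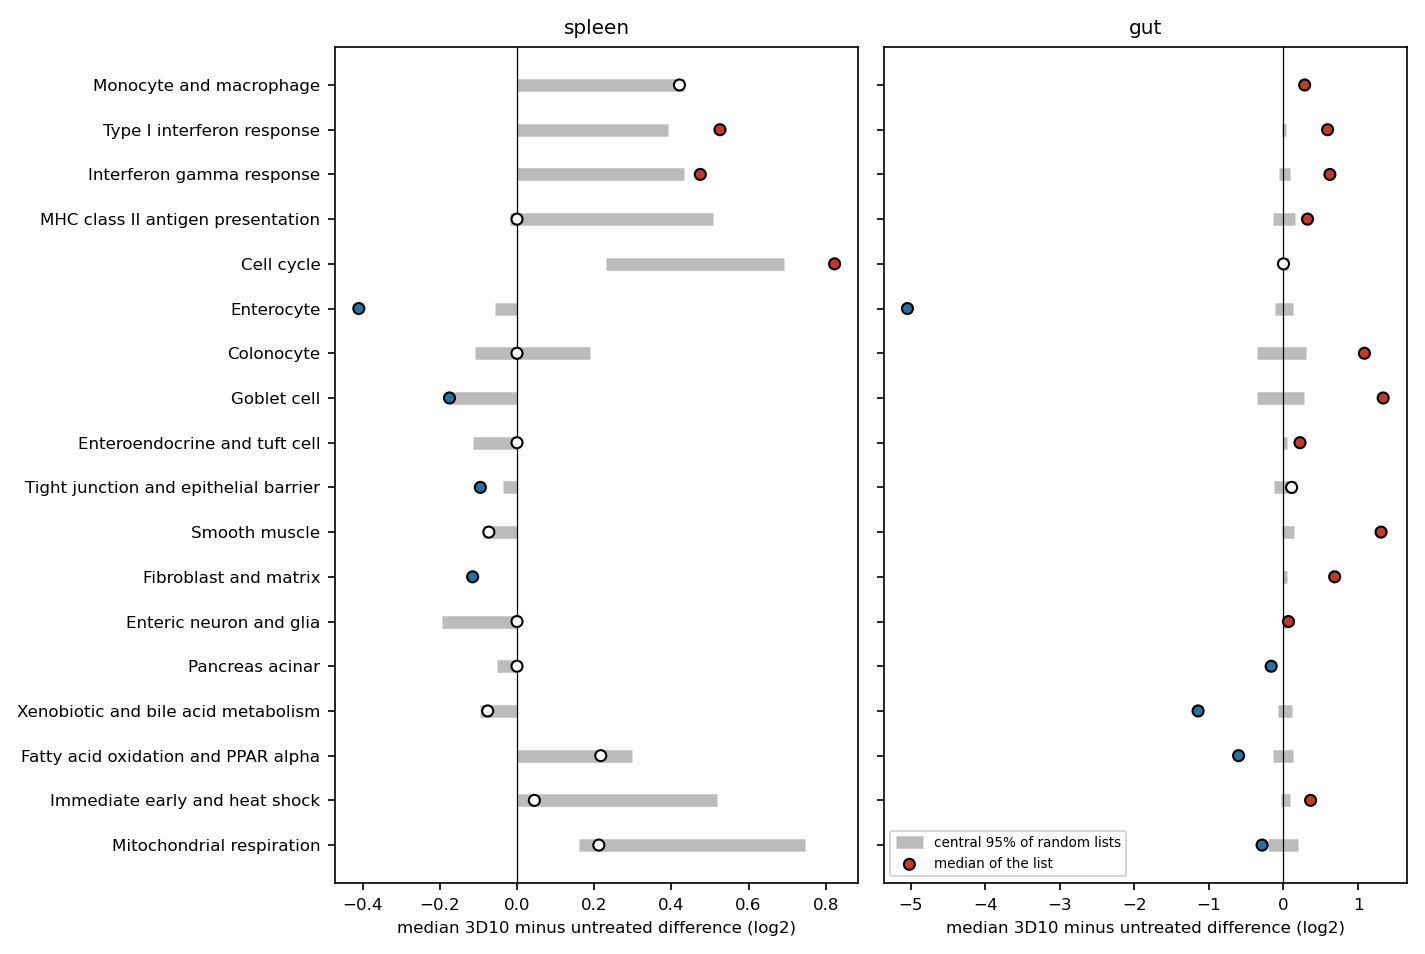
Median 3D10 minus untreated difference (log2, horizontal axis) of each gene list that stood apart in spleen (left) or gut (right), as red points where higher, blue where lower and white where within the central 95% of matched random lists (grey bars). The 2 panels have different scales, with the enterocyte list at -0.41 in spleen and at -5.04 in gut, and both interferon lists stand to the right of the grey bars in each tissue.

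Whether spleen and gut shared a response was asked gene by gene and by limma. Among 9513 genes past the filter in both tissues, 55 were at least 2-fold higher in both, where independent lists would share 27.1 (34 against 13.6 after loess). Lower in both were 6 against 2.3, but 5 against 4.5 after loess and 6 against 4.6 with quantile normalisation, so this excess depended on the scaling. Another 33 were higher in spleen and lower in gut (26.4 for independent lists) and 4 the reverse (2.4). Of the genes higher in both, those with the largest smaller difference included interferon-inducible genes, namely Phf11b (2.09 in spleen and 4.79 in gut), Ifi205 (1.87 and 3.67), Iigp1 (1.85 and 2.44), Gbp10 (1.78 and 1.73) and Slfn4 (1.70 and 3.04). The others were the complement gene C4b (1.87 and 2.41), Car1 (1.68 and 9.36), Klk1 (1.58 and 3.36), Ptcd3 (1.58 and 1.94) and Dym (1.56 and 1.72). The 6 lower in both were Apoa4, Sis, Apoa1, Alpi (-1.98 and -2.74), Anpep (-1.55 and -5.53) and Prap1 (-1.03 and -4.55), of which all but Prap1 belong to the enterocyte list. No gene passed the limma test of a shared difference (0 of 11847 at an FDR of 0.05, smallest adjusted p = 0.715). An unadjusted p under 0.05 was found for 349 genes, where evenly spread p-values would give 592. Genes tied exactly in 1 tissue or both cannot reach such a p in this model, so the shortfall is no evidence on a shared response. With so few degrees of freedom the test could also miss shared differences.

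The difference between the tissues could not be tested with 1 array per tissue and treatment. Set against matched random lists, the spleen difference minus the gut difference stood apart as higher for 8 lists and as lower for 12. The cell cycle list was at 0.85 (percentile 99.69), but at 0.28 and percentile 87.9 after loess, and the enterocyte (4.57), fatty acid oxidation (1.56) and xenobiotic (1.23) lists were also higher. So were the pancreas (0.39), erythroid (0.29), T cell activation (0.22) and megakaryocyte (0.10) lists, but with members past the filter alone they came to percentiles of 47.8, 83.09, 88.61 and 71.63, within the random range. Goblet cell (-1.40), smooth muscle (-1.37), colonocyte (-1.15) and fibroblast (-0.79) lists were lower, as were the interferon gamma (-0.43) and type I interferon (-0.24) lists. The array scale enters these values, since the 4250 genes past the upper quartile filter in spleen had a median difference of 0.48. The remaining lower lists were enteroendocrine (-0.31), progenitor (-0.24), Paneth cell (-0.23), tight junction (-0.16), cholesterol (-0.14) and immediate early (-0.13). Each of these 6 calls was lost under at least 1 alternative, at percentiles of 27.97 for the enteroendocrine list past the filter, 10.3, 11.03 and 13.04 for the progenitor, Paneth cell and cholesterol lists with quantile normalisation, 4.72 for the tight junction list after loess and 3.52 for the immediate early list with unmatched random lists.

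The array labelled no BMT spleen was compared by ranks, with platform and group confounded. T cell and B cell genes ranked low on it for a sample labelled spleen. Whether this came from the sample or from the probes of its platform cannot be told. The progenitor list had a median rank of 85.79 of 100, against 50.42 on the untreated BMT spleen array, and 10 of its 11 members ranked lower after BMT (median difference -31.57, percentile 0.01). The stem and progenitor cell genes Cd34 (93.0 against 46.2), Hoxa9 (92.9 against 36.3), Gata2 (95.6 against 50.4) and Meis1 (79.7 against 18.1) led it. The T cell list had a median rank of 38.84 there and of 73.63 after BMT (median difference 34.79, percentile 99.99), with Cd3g at 6.3 against 86.1 and Cd2 at 10.3 against 74.4. B cell genes ranked low on both arrays, at 27.21 and 35.35. Gaps as wide were found for single ribosomal protein genes. Rpl22 ranked at 18.1 on the untreated BMT spleen array against 99.9 on the array labelled no BMT spleen, and Rps15 at 33.8 against 99.5. The ribosomal protein list as a whole had a median difference of -0.66, within the random range. Of the sex-linked genes, Xist, expressed from the inactive X chromosome, ranked at 98.0 on this array, and the Y-linked Eif2s3y, Kdm5d and Uty at 73.9, 59.6 and 44.6, against 1.0, 4.6 and 2.8 on the untreated BMT spleen array. With averaged probe sets the median rank of the sex-linked list on this array went from 66.73 to 42.42, below the middle.

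Against the array labelled no BMT spleen, 13 lists ranked higher after BMT and 2 lower, the progenitor and the sex-linked list (-48.37). Cytotoxic T cell genes had a median rank difference of 34.71, with Tbx21 at 80.7 against 8.2 and Cd8b1 at 94.7 against 25.5. The 5 measured natural killer genes had the same median, but both medians match Prf1 (79.1 against 44.4), a member of both lists. Of these 5 genes 4 ranked higher after BMT, Gzma and Prf1 of the cytotoxic list among them, and Klre1 ranked lower (3.0 against 14.3). Th1 genes had the largest median difference of the 13, 37.96, with Il18r1 at 76.2 against 8.7. Smaller differences came for MHC class II at 28.15 (within the random range after quantile normalisation, percentile 97.24), immediate early genes at 25.62, monocyte and macrophage genes at 23.41 with C1qb at 83.5 against 7.1, and neutrophil genes at 18.69 with Itgam at 98.7 against 22.3. Chemokine receptor (17.18), colonocyte (16.26), interferon gamma (11.60), chemokine (11.47) and cell cycle (5.04) lists were also higher, of which the colonocyte, interferon gamma and chemokine lists came to percentiles of 90.64, 90.3 and 91.32 with averaged probe sets and the cell cycle list to 89.05 with unmatched random lists. With the 3D10 spleen in place of the untreated one the T cell (25.77), cytotoxic (31.57), Th1 (38.11) and progenitor (-29.52) lists stood apart in the same directions. The chemokine list no longer stood apart (7.56, percentile 96.49). The type I interferon (17.66, percentile 100) and T cell activation (17.53, percentile 99.24) lists came to stand apart as higher, and the mitochondrial list as lower (-4.81, percentile 0.4). Every direction in this comparison rests on a label that the array's lymphocyte and progenitor ranks may put in doubt. Each also crosses platforms, and probe differences between them cannot be told apart from the label.

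**Figure D3:**
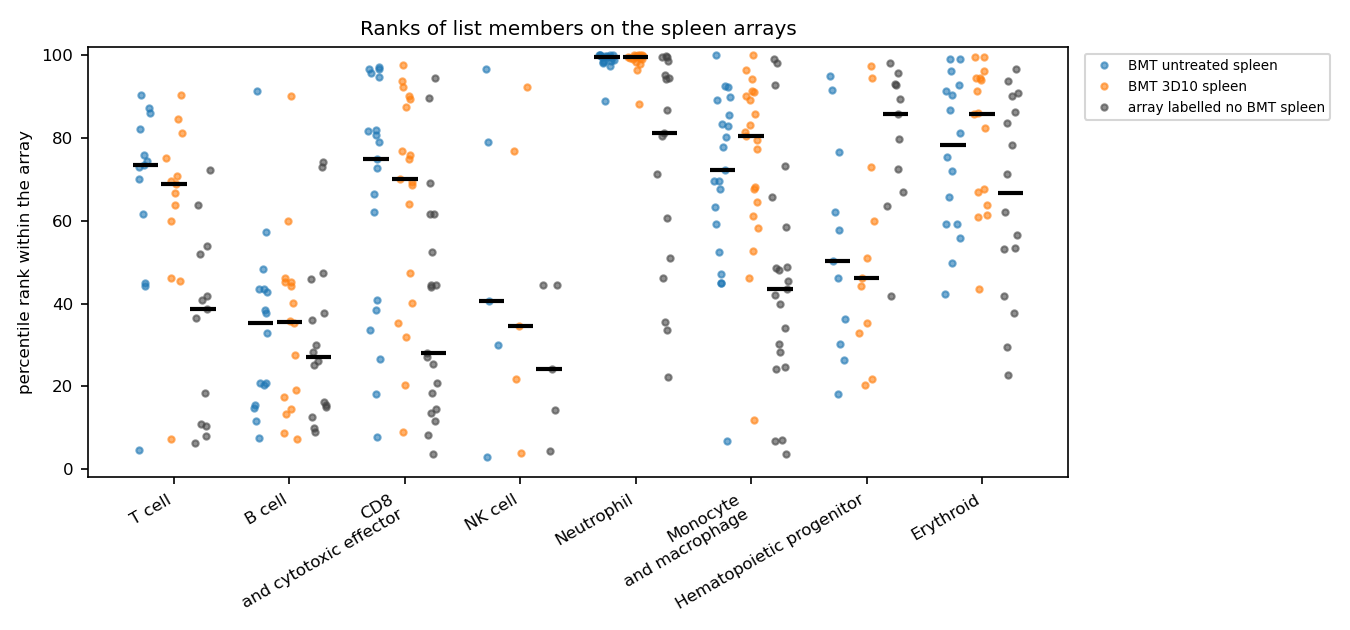
Percentile rank within its array (vertical axis, over 17028 genes on both platforms) of each member of 8 gene lists on the untreated BMT spleen, the 3D10 BMT spleen and the array labelled no BMT spleen, with bars at the medians. Progenitor genes rank highest on the array labelled no BMT spleen (median 85.79), where T cell genes rank lower (38.84) than on the BMT arrays (73.63 and 68.75).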

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

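The tests of gut region, of epithelial loss, of signal range and of the identity of the array labelled no BMT spleen were chosen after the results they bear on had been seen, while the test of gut RNA in spleen was set out before its result. With 1 array per group, none of the differences between tissues below was tested.

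The fibroblast and matrix list moved in opposite directions in the tissues, at -0.115 in spleen and 0.686 in gut with 3D10. The goblet cell list did so too, at -0.175 and 1.337. Neither spleen call held under every setting, with percentiles of 5.87 for the fibroblast list with list means and 23.96 for the goblet cell list past the filter alone. Acot1 was at 2.23 in spleen and -1.06 in gut.

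On the 3D10 gut array enterocyte genes were lower (median difference -5.04) while colonocyte and goblet genes were higher. Loss of epithelium would lower genes of the whole intestinal epithelium as well, and their median was 0.26, which argues against it as the cause of a drop of this size, although Vil1 among them was lower by nearly 2-fold and smooth muscle (1.308) and fibroblast and matrix (0.686) genes were higher, so that a smaller change in the share of epithelium stays open. The test of different stretches of gut asked for a small intestine median below -1 and ileum and colon medians above 1. It failed as set out, since the small intestine median was -2.494 but the colon median 0.302. That colon median lay above matched random lists (percentile 99.99), with 4 members at least 2-fold higher and 0 lower, and was 0.556 over the 10 past the filter. The cutoffs were chosen after the gut values had been seen, so the failure does not decide against different stretches of gut. A narrower version, a more distal stretch of small intestine on the 3D10 array, was framed only after that failure. With an ileum median of 1.091 it may hold, although Cubn (-0.57), Fgf15 (0.00) and Fabp6 (0.37) of the 7 ileum genes were not clearly higher and the colon gene Car1 was (9.36), which it does not predict, and it cannot be told apart from an effect of 3D10 on the epithelium, which stays open as untested, because each condition has 1 gut sample and its lists were drawn up after the gut values had been seen.

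Enterocyte genes were higher on the untreated spleen array than on the 3D10 spleen array. A difference in signal range between the arrays is argued against by loess, after which the list's median was still -0.373 (percentile 0.0). Gut RNA in the untreated spleen sample is a candidate explanation, since 50 other genes high on the untreated gut array and below the filter on the 3D10 spleen array had a median of -0.071 (percentile 0.85, and 0.54 among genes under the same filter, a comparison added afterwards), with 30 below 0 and 0 above. The shift is small, and among genes below the filter on the untreated spleen array instead, 41 high on the 3D10 gut array had a median of -0.005, within the random range (percentile 7.32, but 2.355 among genes under the same filter), while 7 of them high only there were at -0.286 (percentile 2.2), beside -0.365 (percentile 0.26) for 9 of the 50 high only on the untreated gut array, so the source need not be the gut sample measured here. A response of the spleen to 3D10 was not tested.

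On the array labelled no BMT spleen progenitor genes ranked high and lymphocyte genes low. A sample other than whole spleen behind the label is a candidate explanation, since the B cell list had a median rank of 27.21 where textbook spleen is rich in B cells, and the most abundant myeloid granule genes Mpo, Ctsg and Prtn3 ranked at 99.8, 99.7 and 99.7. The same B cell list ranked only at 35.35 on the untreated BMT spleen array, and Mpo ranked at 99.6 there. The neutrophil list, which holds these granule genes, had a lower median rank on the array labelled no BMT spleen (81.26) than on the untreated BMT spleen array (99.52). Of its 17 members 14 ranked higher after BMT and 3 lower. Probe differences between the platforms cannot be told apart from this, because the progenitor shift against the 3D10 spleen (-29.52) also crosses platforms and no other array shares this one's type. The ribosomal protein list also stood apart as lower after BMT with averaged probe sets (-10.53, percentile 0.25) and quantile normalisation (percentile 0.44). By the main ranks it lay within the random range (-0.66, percentile 36.37). The absence of a transplant is the difference the design names, and it stays open as untested.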

How the results depend on the processing

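The alternatives below were fixed before the data were examined. In spleen, genes at least 2-fold higher and lower numbered 290 and 169 with quantile normalisation, 396 and 167 with loess, 2245 and 477 at 1.5-fold and 108 and 15 at 3-fold. Lower genes numbered 208 without the level filter and 36 with it at the upper quartile. In gut, scalings, filters and the probe rule kept both counts within 1.5 times, and thresholds gave 1198 and 1062 at 1.5-fold and 321 and 335 at 3-fold. Genes higher in both tissues numbered 28 with quantile normalisation, 34 with loess, 229 at 1.5-fold and 8 at 3-fold. Those higher in spleen and lower in gut numbered 11, 14, 146 and 1 in this order, and those of the reverse kind 7, 7, 23 and 1. Genes lower in both numbered 23 at 1.5-fold and 3 with the upper quartile filter. A stricter threshold or filter leaves fewer genes by construction, and for the scalings the cause was not tested.

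Lists standing apart as higher in spleen numbered 5 with quantile normalisation, 5 with loess, 7 with list means and 11 with unmatched random lists, against 3. Those lower numbered 1 with list means, against 4. For spleen minus gut, those higher numbered 5 with quantile normalisation, 4 with members past the filter, 5 with list means and 13 with unmatched lists, against 8. Against the array labelled no BMT spleen, lists lower numbered 4 with the mean of probe sets, against 2. Among lists that stood apart in the main setting, 3 turned their sign and passed to the other side of the middle of the random lists. These were the pancreas list in gut (0.038) and the Paneth cell list in spleen minus gut (0.011) with members past the filter, and the erythroid list in spleen minus gut (-0.127) with list means. Lists within the random range could turn as well, as the neutrophil list did after loess in spleen (-0.41 from 0.42) and in spleen minus gut (-0.51 from 0.39). The pancreas list in spleen minus gut came to 0.000 with members past the filter, and the goblet cell list in spleen kept its sign (-0.019) with list means, but both passed to the other side of the middle of the random lists, and the cause was not tested. The interferon gamma and enterocyte lists stood apart in the same direction in both tissues under each alternative run, and the type I interferon list did so except in spleen with averaged probe sets. Of the list differences within a tissue 519 kept their call (standing apart as higher or lower, or within the random range), whatever the sign of a median within it. Another 30 came to stand apart on the side of the middle where they had lain, and 12 did so without having lain there. In 13 the list no longer stood apart. Of the values of named genes 284 stayed on the same side of 2-fold and 4 did not.

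The limma model called 0 genes in each of its settings, with 3 genes at an unadjusted p under 0.05 without the tissue term, 243 with loess and 545 without the filter. The tissue term of the main model pairs the untreated and the 3D10 array of each tissue, which also share a number in their labels, and without this replicate block the model called 0 genes too. Differences of genes near the background, among them the TIM genes, are limited by signal rather than by these choices.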

Other observations

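The fatty acid oxidation list lay within the random range in spleen (median 0.22, percentile 93.85). Of 10 past the filter 4 were at least 2-fold higher, namely Acot1 (2.23), the mitochondrial carnitine transferase Cpt1a (2.06), the lipid droplet protein Plin2 (1.80) and Acadm (1.23), and 0 were lower. In gut the same list had a median of -0.60. The pancreas list had a median of 0.00 in spleen, with Pnliprp1 at 1.68, Ctrb1 at 1.48 and Cpa1 at 1.14 as its members at least 2-fold higher.

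The ER stress list lay within the random range in spleen (median 0.36, percentile 65.65), and 3 of its 13 members past the filter were at least 2-fold higher with 3D10, namely Dnajb9 at 1.84, Hspa5 at 1.13 and Herpud1 at 1.13. The plasma cell list had a median of 0.00, with Jchain at 0.77 and Xbp1 at 0.60. In gut Herpud1 was at -1.62 and Dnajb9 at -0.40.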
